A study of Mus musculus with 18 samples.

How the data were processed

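Messenger RNA was measured by bulk sequencing of stranded, polyA-selected libraries from CD8 T cells sorted out of spleen-cell cultures of P14 mice. The T cell receptor of P14 mice recognises the gp33 peptide of lymphocytic choriomeningitis virus. The mice were wild type (WT) or carried a knockout (KO), limited to CD8 T cells, of TrIP, the protein encoded by Pik3ip1. All cultures lasted 24 h in recombinant IL-2 at 50 U/ml and IL-12 at 2 ng/ml. They received no peptide, gp33 at 100 ng/ml, or gp33 at 100 ng/ml with 10 µM IC87114, an inhibitor of the PI3K delta isoform. The 18 libraries formed 6 groups of 3, with genotype and treatment taken from the sample labels. The protocol text is the same for all samples and describes gp33 for every culture. The titles, library names and treatment fields give it for the stimulated groups only, and these were followed. Library names share a letter across the 3 treatments of each genotype and replicate number. The labels do not say what the letter stands for or that such libraries came from the same animal, so they were not treated as pairs, and the number was used as a block in an alternative.

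The deposited table held 23414 genes by 18 libraries, normalized by the authors in Partek per its name, with values that behave as log2 of a value plus 1. The log base, the offset and the normalization method were not stated. Read as log2, the back-transformed values summed to between 522e3 and 631e3 per library. Read as natural logs the sums were between 9.9 and 13.4 in units of 1e6. The log2 reading was used, and the back-transformed values are called normalized values. They are not whole reads, so the depth of each library is unknown and no counting interval was computed. The aligner and the read counter were not given in the sources used here. The submitters' notes name the genome builds GRCm38 and GRCm39 without their role, so no coordinates are given. Of the 23414 gene identifiers, 23277 (99.4%) were in the gene-name table used here, and 24 had the gene version of GENCODE M21.

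The values were checked against gene length in 9403 of 9415 protein-coding genes (99.9%) with an average normalized value of at least 0.1. Across genes, which are not independent replicates, Spearman's rho was -0.55 with the genomic span and -0.41 with the exonic length. The partial correlation was -0.40 for span given exonic length and -0.06 for exonic length given span. Levels of different genes were therefore not compared with each other. Processed pseudogenes held 54 to 66.8% of the summed values, so values of genes with many processed pseudogenes, such as Gapdh, Ldha, Tpi1, Npm1 and Eno1, depend on how reads were divided among the copies.

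Genes with a normalized value of at least 1 in 3 or more libraries were tested, which left 10257 genes, of which 5800 were protein-coding and 3352 processed pseudogenes. One linear model with a mean per group was fitted to log2(value + 1) with limma 3.58.1 and statmod 1.5.0 in R 4.3.3, with trended and robust empirical Bayes moderation and 12 residual degrees of freedom per gene. Adding 1 before the log makes the fold change of genes with low values smaller than the ratio of their means. Tests were 2-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. There were 9 contrasts, made of 3 between genotypes, 2 for stimulation, 2 for the inhibitor and 2 for the difference between genotypes in a response. Standard errors and adjusted p in the results come from this model. Gene lists, 26 in number, covered T cell programmes, metabolism, interferon responses, survival, stress, mitochondrial transcripts, markers of other cell types and sex genes. The 21 lists with at least 5 genes tested were compared with the other genes by limma camera, with a preset correlation between genes of 0.01 and again with an estimated correlation. Adjustment was over the lists of a comparison. Each list was also counted with its members adjusted over the list alone.

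The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule named Pik3ip1. For each comparison of 2 groups it named the 8 called genes with the largest and the 8 with the smallest log2 fold change whose 3 libraries of a group all lay above the 3 of the other. These genes needed a mean log2(value + 1) of at least 2 and a symbol that is not a predicted gene, clone, pseudogene or receptor segment. For each genotype difference in response it named the 5 largest and the 5 smallest, without the condition on overlap. For each list and comparison it named the 3 members with the smallest p, called or not. A gene named in a comparison could be given in another.

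The tests were run on simulated data of the same size with 10257 genes. Of genes given a log2 fold change of 0.5, 1 or 2, the model called 15 of 67 (22.4%), 44 of 67 (65.7%) and 60 of 66 (90.9%), with 0 in the wrong direction. Of 10057 genes given no change, 4 were called, which was 3.3% of 123 calls. A comparison with no change gave 0 calls. Of 100 random lists of 20 genes, 4 had p under 0.05, and 20 of 20 lists raised by 0.3 were called. The simulated genes varied independently, so this does not test list calls where the members are correlated. Each simulated gene also had the same spread in all 18 libraries. The share of false calls was therefore not tested for groups of unequal spread, as in these data.

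Alternatives tried were pseudocounts of 0.25 and 4, no filter on low values, a filter 5 times as high, median-of-ratios scaling, quantile normalization, the replicate number as a block, an estimated correlation between libraries with the same genotype and number, the libraries of the compared groups only, a log2 fold change of at least 1, and each library left out in turn. A pseudocount of 0.05, protein-coding genes rescaled to a common total, and the removal of replicate 2 of the WT group with inhibitor from every comparison were added after the data were seen. Tests that need whole reads were not run. Python 3.11.15 with scipy 1.17.1 was used for the length check, and matplotlib 3.10.9 for the figures.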

Results

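The data were RNA levels of 23414 genes in 18 libraries of sorted CD8 T cells, 3 in each of 6 groups. WT libraries and libraries labelled KO, in which TrIP (Pik3ip1) should be absent, were each cultured without peptide, with the gp33 antigen, or with gp33 and the PI3K delta inhibitor IC87114. Genes with a value above 0 numbered 18898 to 21180 per library. The sequencing depth of the libraries is unknown. Protein-coding genes held 26 to 32.2% of the summed normalized values and mitochondrially encoded genes 2.7 to 6.7%. The mean correlation of a library with the others of its group was 0.961 for replicate 2 of the WT group with inhibitor, the lowest of the 18 libraries, and reached 0.996. Of the 10257 genes tested, between 474 and 7558 were called in the 7 comparisons of 2 groups.

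Pik3ip1 (ENSMUSG00000034614), the gene whose loss the KO label names, was higher in the libraries labelled KO than in the WT libraries under all 3 conditions. Without peptide its normalized value was 76.1 ± 2.36 (SD, n = 3) in the libraries labelled KO and 31 ± 2.43 (SD, n = 3) in WT, a ratio of 2.46. With gp33 it was 1.61 ± 0.0687 against 0.764 ± 0.105, a ratio of 2.11. With gp33 and inhibitor it was 2.42 ± 0.213 against 0.632 ± 0.0213, a ratio of 3.83. All 3 libraries labelled KO lay above all 3 WT libraries in each condition. The log2 fold changes were 1.27, 0.57 and 1.07, each with an SE of 0.08, and the limma adjusted p were 4.33e-08, 8.35e-05 and 1.32e-06. Stimulation lowered Pik3ip1 in WT (log2 fold change -4.18) and in the libraries labelled KO (-4.89). The values per gene do not show which exons were read. Since the gene goes against the label, each direction given between genotypes is a direction between libraries as labelled, and an exchange of the labels would turn it around. WT likewise means the libraries labelled WT.

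**Figure D1:**
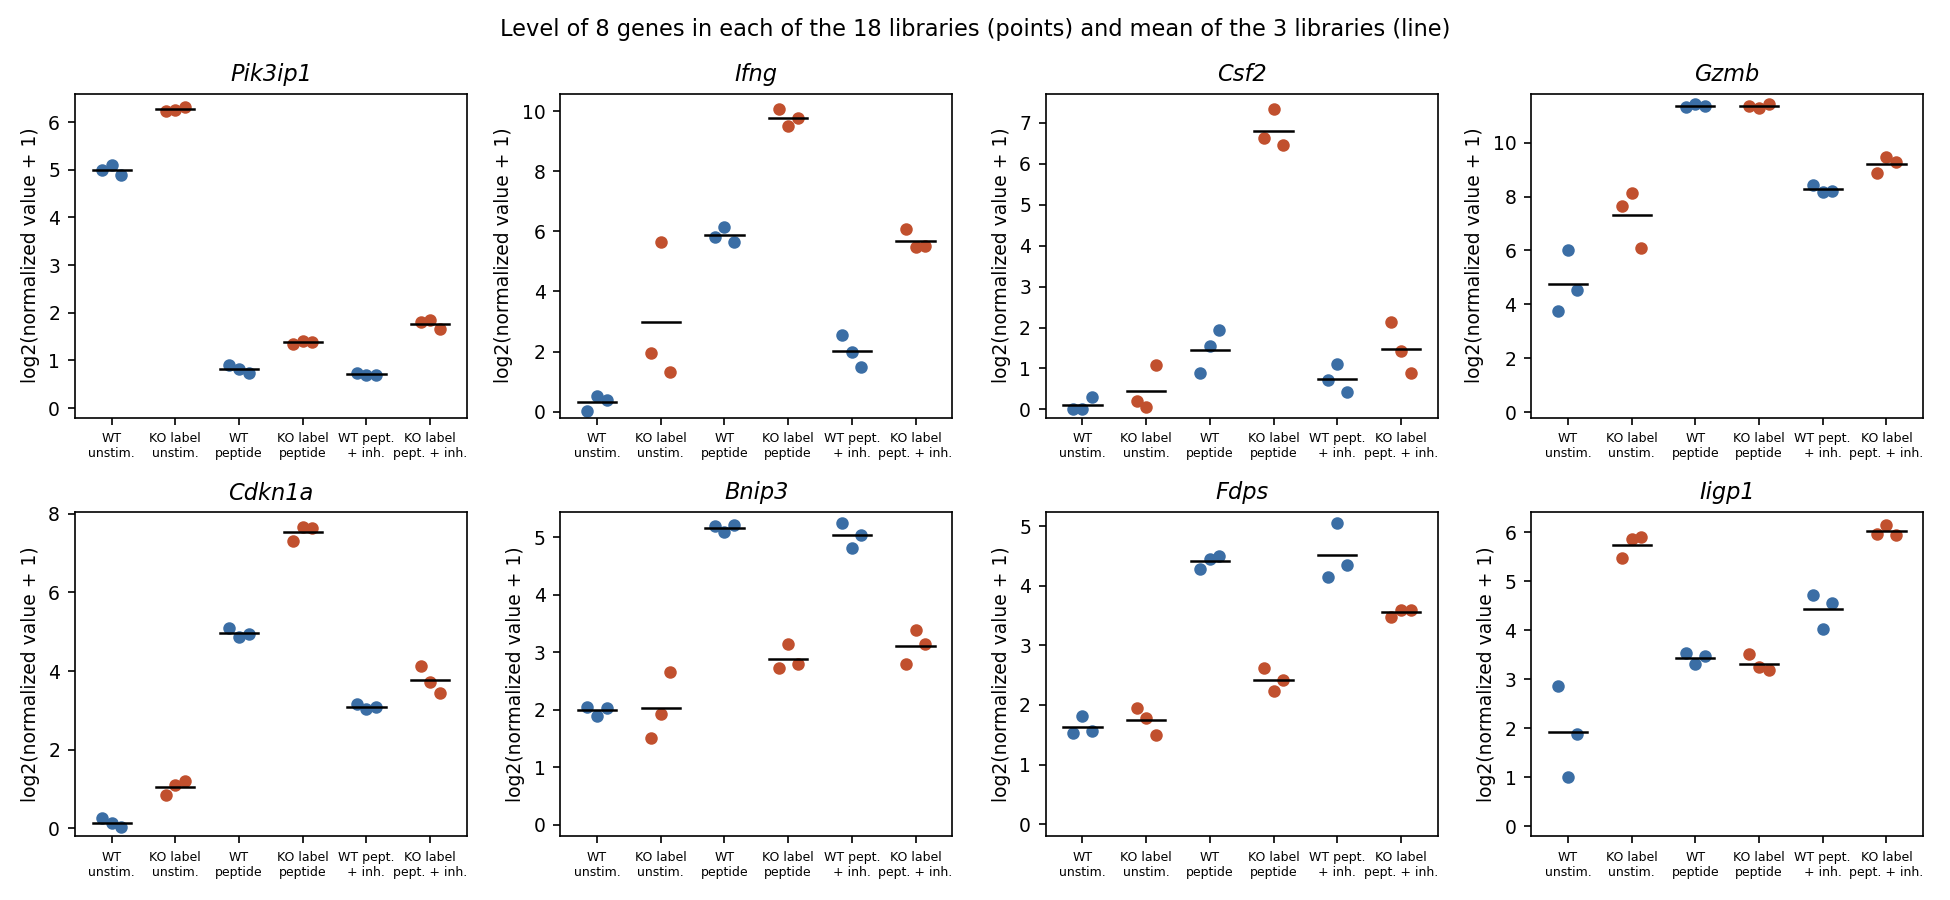
Log2 of the normalized value plus 1 of 8 genes (y axis) in the 6 groups (x axis), with a point per library and a line at the mean of 3. Pik3ip1 lay higher in the libraries labelled KO than in WT in each condition, with mean values of 76.1 and 31 without peptide.

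The comparison of genotypes without peptide asked what differed before antigen. Interferon response genes were higher in the unstimulated libraries labelled KO, a label that Pik3ip1 puts in doubt. Of 18 interferon gamma response genes tested, 17 were higher and 0 lower (18 higher adjusted over the list alone), with a median log2 fold change of 1.37 (adjusted p = 1.68e-24). Of 13 type I interferon response genes, 10 were higher and 0 lower (10 adjusted over the list alone), with a median of 1.17 (adjusted p = 4.12e-14). Iigp1, an interferon-induced GTPase, was at 53 ± 8.35 (SD, n = 3) against 3.33 ± 2.7 in WT (log2 fold change 3.82, SE 0.33, adjusted p = 1.84e-06). Ifitm3, an interferon-induced membrane protein, was at 62.4 ± 23.7 against 0.828 ± 0.727 (log2 fold change 5.15, SE 0.32, adjusted p = 6.7e-08). Ifit3 differed by 2.68 and Gbp2 by 1.85 on the log2 scale. Ly6a, a surface marker of activated T cells, was at 615 ± 19.8 against 65.1 ± 8.12 (log2 fold change 3.23, SE 0.11, adjusted p = 1.04e-10).

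Genes of effector T cells were higher in the same unstimulated libraries labelled KO. Of 13 cytotoxic effector genes, 8 were higher and 0 lower (8 adjusted over the list alone), with a median log2 fold change of 0.66 (adjusted p = 1.22e-08). Gzma, a granzyme, differed by 2.77 (SE 0.25) and Fasl, a death ligand, by 2.10 (SE 0.15). Of 10 effector differentiation genes, 7 were higher and 0 lower (7 adjusted over the list alone), with a median of 0.52 (adjusted p = 7.93e-09), among them the chemokine receptor Cxcr3 at 3.18 and the transcription factor Eomes at 1.54. Of 16 cytokine and chemokine genes, 8 were higher and 0 lower (10 adjusted over the list alone; median 0.56, adjusted p = 4.53e-05). Ifng was called at 2.66 (SE 0.75, adjusted p = 0.0316), with values of 2.87, 48.6 and 1.5 in the libraries labelled KO. Its SE comes from a spread shared by all 6 groups, not from the unstimulated libraries alone. The Ifng call ended without WT unstimulated replicate 1, 2 or 3 (adjusted p of 0.056 to 0.089). Of 16 glycolysis genes, 10 were higher and 0 lower (11 adjusted over the list alone; median 0.42, adjusted p = 5.17e-09), with Tpi1 at 1.67 and Eno1 at 0.99, both of which have processed pseudogenes. FOXO targets were lower in 8 of 15 and higher in 0 (10 lower adjusted over the list alone; median -0.40, adjusted p = 2.86e-06), with Sesn1 at -0.78 and Klf2 at -0.55. Naive and memory genes, which share Klf2, Il7r, S1pr1 and Ccr7 among others with that list, were lower in 5 of 16 and higher in 1 (8 and 1 adjusted over the list alone; median -0.18, adjusted p = 9.41e-05).

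Markers of other cell types moved with the same comparison. Of 6 myeloid and dendritic markers tested, 4 were higher and 0 lower in the unstimulated libraries labelled KO (6 higher adjusted over the list alone; median log2 fold change 2.06, adjusted p = 3.96e-05), with the neutrophil gene S100a8 at 31.1 ± 18.7 against 0.247 ± 0.427. Of 10 B cell markers, 8 were lower and 0 higher (8 adjusted over the list alone; median -0.86, adjusted p = 9.48e-08), with Fcmr at -1.03 and Fcer2a at -1.12. Igkc, the kappa light chain gene, was at 2250, 1380 and 20500 in the 3 unstimulated libraries labelled KO and at 6480, 2680 and 6260 in WT. MHC class II genes were lower in 6 of 9 and higher in 0 (6 lower and 1 higher adjusted over the list alone; median -0.65, adjusted p = 0.0031), with an adjusted p = 0.279 with an estimated correlation. Of the NK cell list only Fcer1g and Tyrobp were tested, and both were higher, at 1.67 and 1.66. Other members of that list, such as Ncr1 and Klrb1c, were not among the genes tested. Fcer1g and Tyrobp alone do not show a change in NK cells. The erythroid markers tested, Hba-a1 and Hba-a2, were higher at 1.37 and 1.61, and both calls ended without KO unstimulated replicate 2. Of the CD4 T cell list, Tnfrsf25 was called at 0.50, and Cd5 was at -0.18 (adjusted p = 0.346). The call for Tnfrsf25 ended without KO unstimulated replicate 1 or 2 or WT unstimulated replicate 2. Tnfrsf25 and Cd5 alone do not show a change in CD4 T cells. Both Y-linked genes tested were expressed in all groups, with Ddx3y at -0.38 (adjusted p = 0.00263) and Eif2s3y at -0.24 (adjusted p = 0.191). Of 26 cell cycle genes, 2 were higher and 0 lower (2 adjusted over the list alone; adjusted p = 0.00144), with an adjusted p = 0.421 with an estimated correlation. The lists for T cell activation, inhibitory receptors, amino acid uptake and one-carbon metabolism, cholesterol synthesis, fatty acid synthesis, ribosome biogenesis, survival and apoptosis, stress and immediate early genes, and mitochondrially encoded genes were not called, with adjusted p from 0.0549 for inhibitory receptors to 0.929 for mitochondrially encoded genes. Of 24 PI3K pathway components, 4 were tested and 0 called in this comparison, at an adjusted p of 0.255 for Akt1 and 0.139 for Rheb.

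In total 1326 of 10257 genes were called between the unstimulated groups, 584 higher and 742 lower in the libraries labelled KO, and 225 of them differed by a log2 fold change of at least 1, of which 161 were higher and 64 lower. The list calls of this comparison other than MHC class II and cell cycle held with an estimated correlation. Which direction had more calls depended on the setting: the share higher was 44%, 28.4% with protein-coding genes alone, rescaled, 53.2% with a filter 5 times as high and 64.8% from the 6 libraries compared. The count was 466 from the 6 libraries compared, 302 higher and 164 lower, and 2101 without replicate 2 of the WT group with inhibitor, which is in neither group but enters the shared spread.

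With gp33, the comparison of genotypes asked what differed 24 h after antigen. Cytokine genes, cytotoxic genes, and survival and apoptosis genes were higher in the stimulated libraries labelled KO, a label that Pik3ip1 puts in doubt. Of 16 cytokine and chemokine genes, 10 were higher and 1 lower (12 and 2 adjusted over the list alone), with a median log2 fold change of 1.66 (adjusted p = 5.88e-07). Ifng, the main effector cytokine of CD8 T cells, was at 896 ± 185 (SD, n = 3) against 58.4 ± 10.8 in WT (log2 fold change 3.91, SE 0.75, adjusted p = 0.0017). Csf2, which encodes GM-CSF, was at 115 ± 40.4 against 1.86 ± 0.979 (log2 fold change 5.35, SE 0.36, adjusted p = 1.01e-07). Il3 was at 48.2 ± 7.17 against 3.43 ± 0.49 (log2 fold change 3.47, SE 0.19, adjusted p = 1.16e-08), and Il2 at 31.5 ± 4.23 against 5.64 ± 0.552. Of 13 cytotoxic effector genes, 9 were higher and 0 lower (9 adjusted over the list alone; median 1.01, adjusted p = 2.88e-07), with Gzmc at 2.89 and Fasl at 1.92, while Gzmb was at -0.01 (adjusted p = 0.991). Of 10 effector differentiation genes, 6 were higher and 0 lower (6 adjusted over the list alone; median 0.51, adjusted p = 0.000313), with Cxcr6 at 1.52 and Cxcr3 at 1.41.

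Survival and apoptosis genes were higher in 13 of 17 and lower in 0 of the stimulated libraries labelled KO compared with WT (13 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.89 (adjusted p = 1.99e-09). The members that moved most were Pmaip1, a pro-apoptotic BH3-only gene, at 47.1 ± 3.88 (SD, n = 3) against 6.02 ± 0.283, Cdkn1a, which encodes the cell cycle inhibitor p21, at 186 ± 23.5 against 30.1 ± 2.5, and Mdm2, which encodes a ubiquitin ligase of p53, at 27.5 ± 6.05 against 4.3 ± 0.783. Their log2 fold changes were 2.77, 2.58 and 2.42. Phlda3, another p53 target, was at 57.3 ± 13.7 against 6.54 ± 1.58 (log2 fold change 2.95, SE 0.20, adjusted p = 1.22e-07). Stress and immediate early genes were higher in 12 of 16 and lower in 2 (13 and 2 adjusted over the list alone; median 0.81, adjusted p = 3.06e-06, and adjusted p = 0.0512 with an estimated correlation), with Fos at 2.13. Type I interferon response genes were higher in 8 of 13 and lower in 0 (8 adjusted over the list alone; median 0.89, adjusted p = 3.68e-07), with Isg15 at 1.62. Interferon gamma response genes were not called as a list (3 higher and 3 lower of 18, 4 and 5 adjusted over the list alone, adjusted p = 0.19), with Cxcl10 at 1.96 and Gbp2 at -1.04. T cell activation genes were higher in 7 of 19 and lower in 1 (9 and 1 adjusted over the list alone; median 0.34, adjusted p = 0.00189, and adjusted p = 0.0512 with an estimated correlation), with Nr4a2 at 1.70 and Rel at 0.99. FOXO targets were higher in 7 of 15 and lower in 0 (7 and 2 adjusted over the list alone; median 0.38, adjusted p = 0.000388, and adjusted p = 0.101 with an estimated correlation), with Trp53inp1 at 2.28 and Txnip at 1.04.

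Genes of glycolysis and lipid synthesis were lower in the stimulated libraries labelled KO. Of 18 cholesterol synthesis genes, 15 were lower and 0 higher (15 adjusted over the list alone), with a median log2 fold change of -0.77 (adjusted p = 1.1e-13). Fdps, an enzyme of the mevalonate pathway, was at 4.4 ± 0.73 (SD, n = 3) against 20.3 ± 1.65 (log2 fold change -1.98, SE 0.19, adjusted p = 3.92e-06), and Acat2 differed by -1.03. Of 16 glycolysis genes, 15 were lower and 0 higher (15 lower and 1 higher adjusted over the list alone; median -0.63, adjusted p = 2.02e-11), with the glucose transporter Slc2a3 at -0.85, Gpi1 at -0.73 and Pgam1 at -0.61. Of 6 fatty acid synthesis genes, 4 were lower and 0 higher (5 lower adjusted over the list alone; median -0.30, adjusted p = 0.000313), with the desaturases Scd2 at -1.49 and Scd1 at -0.72. Bnip3, a mitophagy receptor induced by low oxygen, was at 6.46 ± 1.17 against 35.1 ± 1.55 (log2 fold change -2.28, SE 0.23, adjusted p = 5.73e-06). Ctla4, an inhibitory receptor, was at 2.63 ± 0.479 against 8.41 ± 0.165 (log2 fold change -1.38, SE 0.10, adjusted p = 1.17e-07). Cell cycle genes were lower in 8 of 26 and higher in 1 (8 and 1 adjusted over the list alone; median -0.23, adjusted p = 0.00137, and adjusted p = 0.447 with an estimated correlation), with Plk1 at -0.70. Amino acid uptake and one-carbon metabolism genes (adjusted p = 0.0131, and adjusted p = 0.186 with an estimated correlation) were higher in 7 of 16 and lower in 1 (8 and 2 adjusted over the list alone; median 0.22). Although Ctla4 was lower, inhibitory receptor genes as a list were higher in 5 of 10 and lower in 2 (7 and 2 adjusted over the list alone; median 0.35, adjusted p = 0.0434, and adjusted p = 0.0836 with an estimated correlation). Naive and memory genes were higher in 7 of 16 and lower in 1 (7 and 2 adjusted over the list alone; median 0.16, adjusted p = 0.0434, and adjusted p = 0.231 with an estimated correlation). Both of these list calls ended without KO stimulated replicate 2 or 3 or WT stimulated replicate 1. B cell and myeloid markers were not called as lists between the stimulated groups (adjusted p = 0.745 and 0.19). Fcer1g and Tyrobp of the NK cell list were higher at 0.76 and 0.63, and Tnfrsf25 and Cd5 of the CD4 T cell list at 0.80 and 0.37. The calls for Tyrobp and Cd5 ended without any 1 of the 6 libraries compared, and that for Fcer1g without KO stimulated replicate 2 or 3 or WT stimulated replicate 2. The calls for cytokines, cytotoxic effector, effector differentiation, survival, type I interferon, cholesterol, glycolysis and fatty acid lists held with an estimated correlation.

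In total 2457 genes were called between the stimulated groups, 1525 higher and 932 lower in the libraries labelled KO, and 327 of them at a log2 fold change of at least 1. With protein-coding genes alone, rescaled, the share of calls that were higher went from 62.1% to 74.8%, and with a filter 5 times as high to 49.3%. The count was 1582 without KO stimulated replicate 2, 1605 without WT stimulated replicate 3, and 3968 from the 6 libraries compared.

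**Figure D2:**
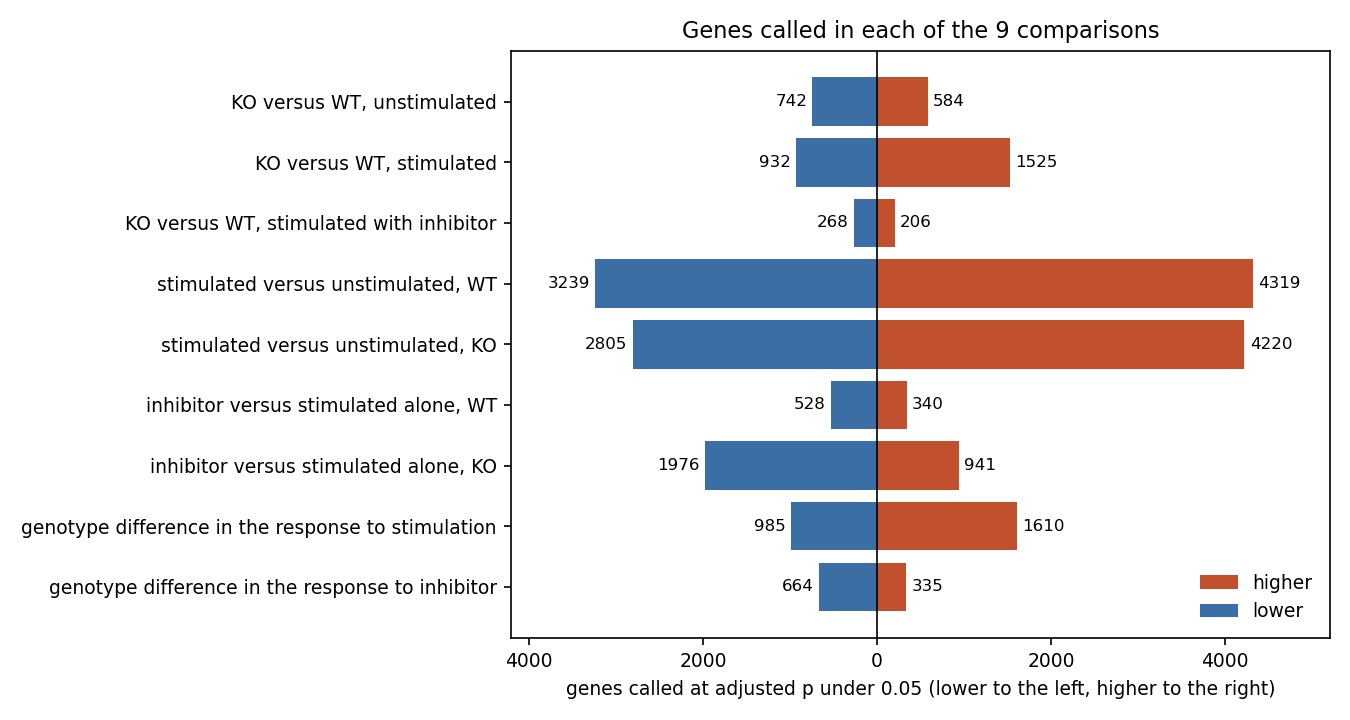
Number of genes called in each of the 9 comparisons, with genes higher and genes lower drawn as separate bars from 0. Stimulation gave 7558 calls in WT and 7025 in the libraries labelled KO, and the genotype comparison with inhibitor gave 474.

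With gp33 and inhibitor, the comparison of genotypes asked which differences were seen while PI3K delta was inhibited. Glycolysis and cholesterol genes were again lower in the libraries labelled KO, and cytotoxic and effector differentiation genes higher. Of 16 glycolysis genes, 14 were lower and 0 higher (14 adjusted over the list alone; median log2 fold change -0.53, adjusted p = 4.64e-14), with Slc2a3 at -0.54 and Pgk1 at -0.70. Of 18 cholesterol synthesis genes, 7 were lower and 0 higher (12 lower adjusted over the list alone; median -0.29, adjusted p = 3.45e-08), with Mvd at -0.70. Cytotoxic effector genes were higher in 4 of 13 and lower in 0 (6 higher adjusted over the list alone; median 0.35, adjusted p = 1.36e-05), with the granzyme inhibitor Serpinb9 at 1.61. Effector differentiation genes were higher in 3 of 10 and lower in 0 (5 higher adjusted over the list alone; median 0.20, adjusted p = 6.38e-05), with Cxcr3 at 1.95 and Tbx21, which encodes T-bet, at 0.85. These 4 list calls held with an estimated correlation. Batf3, a transcription factor, was at 6.49 ± 1.06 (SD, n = 3) against 0.628 ± 0.0557 in WT (log2 fold change 2.19, SE 0.12, adjusted p = 1.73e-07). Bnip3 was at 7.73 ± 1.76 against 32.1 ± 4.97 (log2 fold change -1.93, SE 0.23, adjusted p = 0.00018).

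Ifng was at 51.6 ± 12.7 (SD, n = 3) with inhibitor in the libraries labelled KO against 3.2 ± 1.51 in WT (log2 fold change 3.68, SE 0.75, adjusted p = 0.0106). The call ended without replicate 1 of the group labelled KO with inhibitor (adjusted p = 0.051). The SE comes from a spread shared by all 6 groups, among them the unstimulated libraries labelled KO at 2.87, 48.6 and 1.5. With inhibitor the libraries labelled KO (66.3, 43.5 and 45.1) all lay above those of WT (4.82, 2.97 and 1.83). The cytokine and chemokine list was not called (2 higher and 1 lower of 16, 4 and 2 adjusted over the list alone, adjusted p = 0.227). Interferon gamma response genes were higher in 4 of 18 and lower in 0 (8 higher adjusted over the list alone; median log2 fold change 0.30, adjusted p = 4.1e-05, and adjusted p = 0.259 with an estimated correlation). MHC class II genes were lower in 2 of 9 and higher in 0 (2 adjusted over the list alone; adjusted p = 0.00295, and adjusted p = 0.42 with an estimated correlation), with H2-Ab1 at -1.62. Mitochondrially encoded genes were higher in 1 of 13 (4 adjusted over the list alone; adjusted p = 0.00459, and adjusted p = 0.42 with an estimated correlation). In total 474 genes were called, 206 higher and 268 lower, with 82 at a log2 fold change of at least 1, of which 43 were higher and 39 lower. The share higher was 43.5%, 32.5% with protein-coding genes alone, rescaled, and 61.5% from the 6 libraries compared (67 higher and 42 lower). The count was 274, 261 and 294 without replicate 1, 2 or 3 of the group labelled KO with inhibitor, and 109 from the 6 libraries compared.

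Stimulation asked how each genotype responded to gp33. In WT naive and memory genes fell and T cell activation genes rose. T cell activation genes were higher in 16 of 19 and lower in 0 (16 adjusted over the list alone), with a median log2 fold change of 1.39 (adjusted p = 1.07e-05), with the IL-2 receptor chain Il2ra at 3.35. Naive and memory genes were lower in 15 of 16 and higher in 0 (15 adjusted over the list alone; median -1.75, adjusted p = 2.25e-08). S1pr1, the receptor for exit from lymphoid tissue, fell from 271 ± 9.93 (SD, n = 3) to 2.28 ± 0.399 (log2 fold change -6.38, SE 0.11, adjusted p = 4.96e-15), and Il7r differed by -4.57. Gzmb rose from 32.7 ± 27 to 2648 ± 86.6 (log2 fold change 6.60, SE 0.49, adjusted p = 1.66e-08). Ifng rose from 0.256 ± 0.218 to 58.4 ± 10.8. These 2 list calls held with an estimated correlation. Other lists were called in WT with the preset correlation and not with an estimated one. Among these, glycolysis genes were higher in 16 of 16 (16 adjusted over the list alone; median 2.28, adjusted p = 9.52e-08, and adjusted p = 0.0651 with an estimated correlation), ribosome biogenesis genes in 21 of 21 (21 adjusted over the list alone; median 1.13, adjusted p = 3.87e-06, and adjusted p = 0.148 with an estimated correlation) and cell cycle genes in 25 of 26 (25 adjusted over the list alone; median 2.09, adjusted p = 4.35e-09, and adjusted p = 0.148 with an estimated correlation). B cell markers were lower in 10 of 10 in WT (10 adjusted over the list alone; median -3.00, adjusted p = 1.51e-06, and adjusted p = 0.0657 with an estimated correlation), and so were MHC class II genes in 9 of 9 (9 adjusted over the list alone; median -2.87, adjusted p = 1.14e-06, and adjusted p = 0.0903 with an estimated correlation). Fcer1g and Tyrobp of the NK cell list were lower at -0.90 and -0.98.

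In the libraries labelled KO, stimulation raised 19 of 19 T cell activation genes (19 adjusted over the list alone; median log2 fold change 1.86, adjusted p = 2.11e-07) and 9 of 10 inhibitory receptor genes (9 adjusted over the list alone; median 1.36, adjusted p = 0.000466), with Lag3 at 2.54. It lowered 14 of 16 naive and memory genes and raised 1 (14 and 1 adjusted over the list alone; median -1.59, adjusted p = 2.39e-08). These calls held with an estimated correlation. Genes of the interferon gamma response were lower in 15 of 18 and higher in 1 (15 and 1 adjusted over the list alone; median -2.09, adjusted p = 7e-08, and adjusted p = 0.0695 with an estimated correlation), with Irf1 at -2.58. Glycolysis genes were higher in 15 of 16 and lower in 1 (15 and 1 adjusted over the list alone; median 1.12, adjusted p = 0.000162, and adjusted p = 0.139 with an estimated correlation). Cdkn1a rose from 1.08 ± 0.257 to 186 ± 23.5 (SD, n = 3; log2 fold change 6.49, SE 0.15, adjusted p = 1.12e-13). B cell markers were lower in 10 of 10 (10 adjusted over the list alone; median -2.35, adjusted p = 2.74e-06, and adjusted p = 0.0695 with an estimated correlation), and MHC class II genes in 9 of 9 (9 adjusted over the list alone; median -2.47, adjusted p = 3.62e-07, and adjusted p = 0.0695 with an estimated correlation). Fcer1g and Tyrobp were lower at -1.81 and -2.01, and the erythroid markers Hba-a1 and Hba-a2 at -1.33 and -1.42. Myeloid and dendritic markers were lower in 4 of 6 and not called as a list (adjusted p = 0.106).

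Stimulation changed 7558 genes in WT (4319 higher, 3239 lower) and 7025 in the libraries labelled KO (4220 higher, 2805 lower), with 3475 and 2806 at a log2 fold change of at least 1. Of these genes, 3396 were higher in both genotypes and 2387 lower in both, against 1777 and 886 for independent calls, and the log2 fold changes had a Pearson r of 0.86 across genes, which are not independent replicates. The median log2 fold change of all genes was 0.19 in WT and 0.20 in the libraries labelled KO, and -0.07 and -0.06 with median-of-ratios scaling. That scaling took the share of calls that were higher from 57.1% to 44.8% in WT and from 60.1% to 45.2% in the libraries labelled KO.

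The contrast of the stimulation responses tested whether the genotypes responded differently. Survival and apoptosis genes had higher responses, and glycolysis and interferon gamma response genes lower ones, in the libraries labelled KO, a label that Pik3ip1 puts in doubt. Responses are signed, so a higher response is a larger rise or a smaller fall in these libraries than in WT. Survival and apoptosis genes had a higher response in 10 of 17 and a lower in 0 (10 adjusted over the list alone; median difference 0.67 log2, adjusted p = 3.93e-06). Pmaip1 was at 6.22 ± 0.192 (SD, n = 3) without and 6.02 ± 0.283 with gp33 in WT, and at 8.78 ± 0.34 and 47.1 ± 3.88 in the libraries labelled KO, a difference of 2.34 (SE 0.14, adjusted p = 1.49e-07). FOXO targets had a higher response in 10 of 15 and a lower in 0 (11 higher adjusted over the list alone; median 0.97, adjusted p = 2.4e-07), with S1pr1 at 1.53. Glycolysis genes had a lower response in 14 of 16 and a higher in 0 (15 lower adjusted over the list alone; median -1.11, adjusted p = 1.36e-13), with Gpi1 at -1.25. Cholesterol synthesis genes had a lower response in 12 of 18 and a higher in 0 (15 lower adjusted over the list alone; median -0.57, adjusted p = 2.37e-07), with Fdps at -2.09. Interferon gamma response genes had a lower response in 15 of 18 and a higher in 0 (16 lower adjusted over the list alone; median -1.56, adjusted p = 1.36e-13), with Gbp2 at -2.89. These 5 calls held with an estimated correlation. The type I interferon response was not called (0 higher and 4 lower of 13, adjusted p = 0.0617). B cell markers had a higher response in 5 of 10 and a lower in 0 (8 higher adjusted over the list alone; median 0.89, adjusted p = 0.000921, and adjusted p = 0.213 with an estimated correlation). Myeloid and dendritic markers had a lower response in 3 of 6, and MHC class II genes a higher in 5 of 9 and a lower in 2, neither called as a list (adjusted p = 0.0617 for both). Fcer1g and Tyrobp were at -0.91 and -1.02, calls that ended without 8 and 2 of 13 libraries left out in turn. In total 2595 genes were called, 1610 with a higher and 985 with a lower response, with 626 at a difference of at least 1. With protein-coding genes alone, rescaled, the share higher went from 62% to 78.2%, and with a filter 5 times as high to 48.8%. The count was 3882 without replicate 2 of the WT group with inhibitor.

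**Figure D3:**
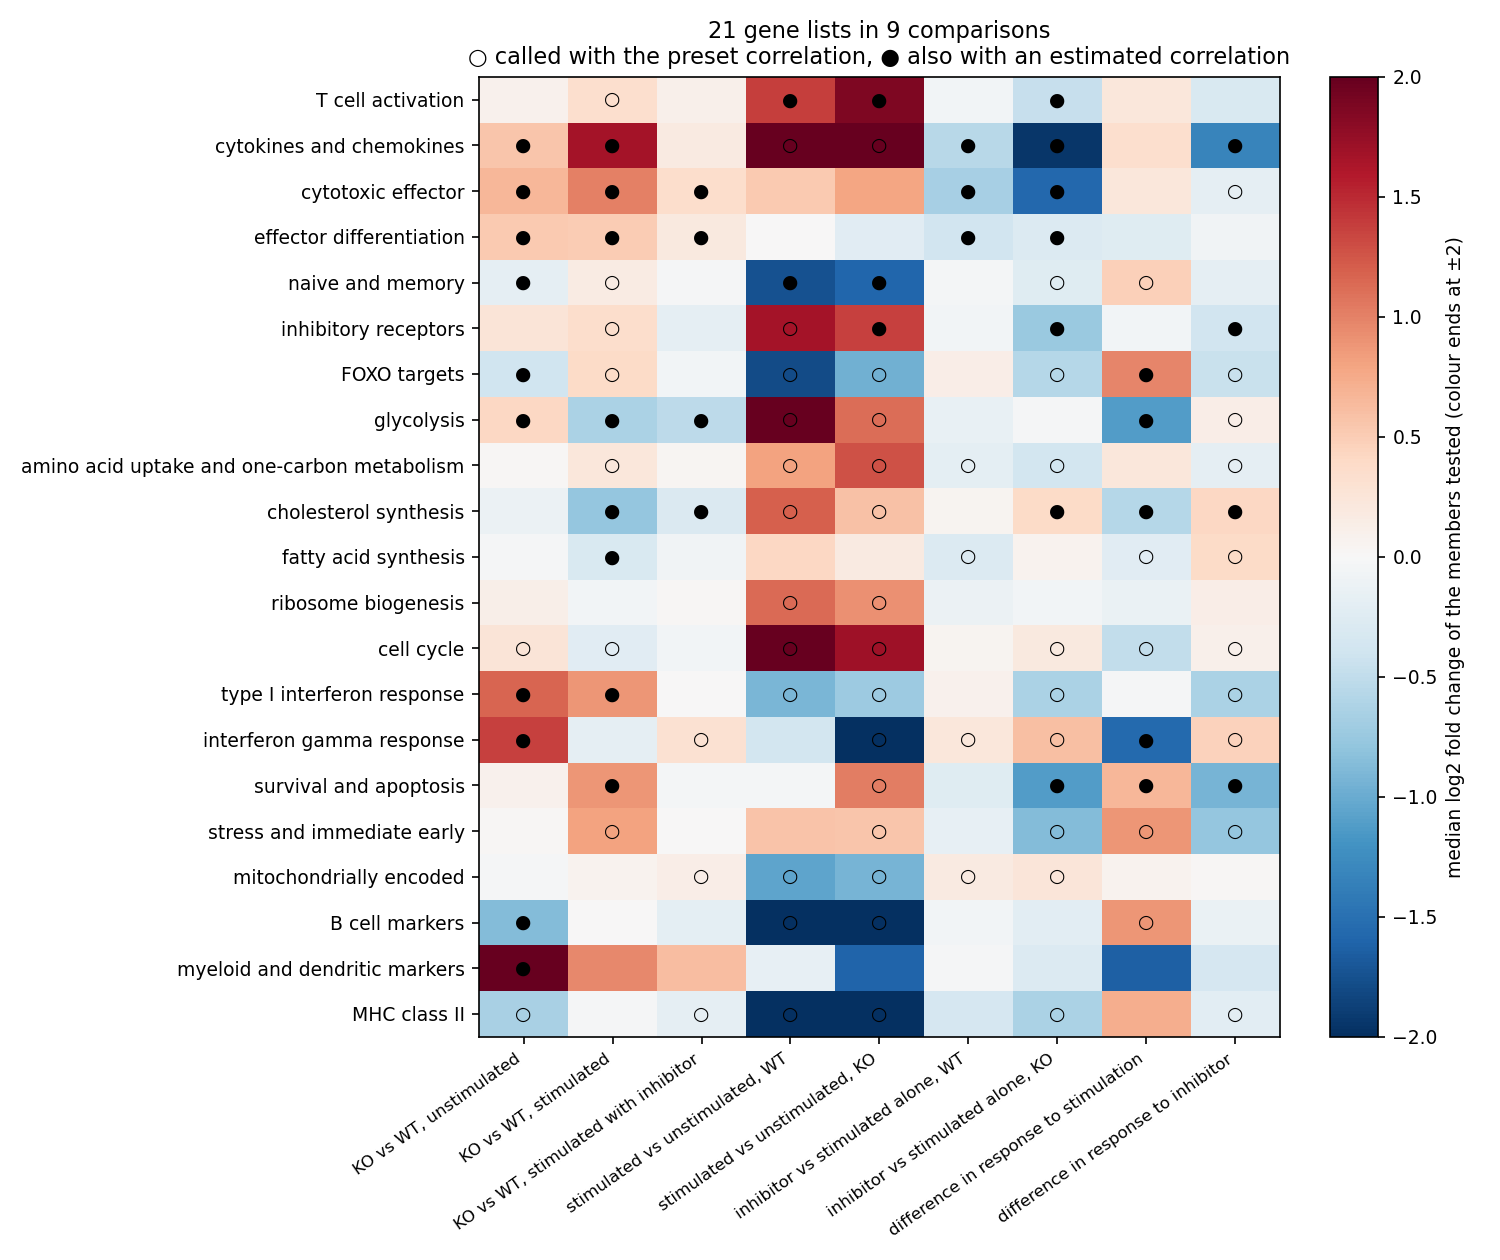
Median log2 fold change of the tested members of each of 21 gene lists in each of the 9 comparisons, in colour, with list calls marked. Interferon gamma response genes had a median of 1.37 between genotypes without peptide, and cytokine genes -1.95 for the inhibitor in the libraries labelled KO.

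The inhibitor comparisons asked what IC87114 changed in stimulated cells. In WT it lowered effector genes. Of 13 cytotoxic effector genes, 9 were lower and 1 higher (9 and 1 adjusted over the list alone; median log2 fold change -0.66, adjusted p = 1.63e-07). Gzmb fell from 2648 ± 86.6 (SD, n = 3) to 311 ± 31.2 (log2 fold change -3.09, SE 0.49, adjusted p = 0.00124), and Prf1, which encodes perforin, differed by -1.97. Of 16 cytokine and chemokine genes, 7 were lower and 1 higher (7 and 1 adjusted over the list alone; median -0.56, adjusted p = 0.000728), with Ifng at -3.87 (SE 0.75, adjusted p = 0.00548), Xcl1 at -3.11 and Lta at -2.67. Effector differentiation genes were lower in 5 of 10 and higher in 0 (6 lower adjusted over the list alone; median -0.38, adjusted p = 0.000728), with Tbx21 at -0.94. These 3 list calls held with an estimated correlation. Fatty acid synthesis genes were lower in 3 of 6 and higher in 0 (4 lower adjusted over the list alone; adjusted p = 0.00798, and adjusted p = 0.183 with an estimated correlation), with Scd1 at -0.62. Responders to interferon gamma were higher in 3 of 18 and lower in 0 (5 higher adjusted over the list alone; adjusted p = 0.000861, and adjusted p = 0.378 with an estimated correlation). In total 868 genes were called, 340 higher and 528 lower, with 80 at a log2 fold change of at least 1. The share higher went from 39.2% to 55.2% with median-of-ratios scaling and to 57.7% with quantile normalization. The count was 433 and 452 without WT stimulated replicate 1 or 2, 534 without replicate 3, and 263 from the 6 libraries compared.

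In the libraries labelled KO the inhibitor lowered cytokine genes, cytotoxic genes, and survival and apoptosis genes, and raised cholesterol genes. Of 16 cytokine and chemokine genes, 13 were lower and 0 higher (14 lower adjusted over the list alone; median log2 fold change -1.95, adjusted p = 7.77e-10). Csf2 fell from 115 ± 40.4 (SD, n = 3) to 1.98 ± 1.31 (log2 fold change -5.33, SE 0.36, adjusted p = 9.07e-08), and Il3 differed by -4.73. Cytotoxic effector genes were lower in 11 of 13 and higher in 1 (11 and 1 adjusted over the list alone; median -1.57, adjusted p = 7.07e-08). Survival and apoptosis genes were lower in 14 of 17 and higher in 0 (14 adjusted over the list alone; median -1.11, adjusted p = 7.77e-10), with Cdkn1a at -3.78 and Mdm2 at -2.67. T cell activation genes were lower in 10 of 19 and higher in 1 (10 and 1 adjusted over the list alone; median -0.46, adjusted p = 0.00103), inhibitory receptor genes lower in 7 of 10 and higher in 1 (7 and 1 adjusted over the list alone; median -0.74, adjusted p = 0.00245), and effector differentiation genes lower in 5 of 10 and higher in 0 (6 lower adjusted over the list alone; median -0.27, adjusted p = 0.00103). Cholesterol synthesis genes were higher in 13 of 18 and lower in 0 (13 adjusted over the list alone; median 0.38, adjusted p = 1.38e-07). These 7 list calls held with an estimated correlation. Interferon gamma response genes were higher in 12 of 18 and lower in 1 (12 and 1 adjusted over the list alone; median 0.60, adjusted p = 7.66e-08, and adjusted p = 0.0596 with an estimated correlation), with Iigp1 at 2.71 and Gbp2 at 1.80. Type I interferon response genes instead were lower in 8 of 13 and higher in 0 (8 adjusted over the list alone; median -0.64, adjusted p = 0.00027, and adjusted p = 0.125 with an estimated correlation). MHC class II genes were lower in 6 of 9 and higher in 0 (6 adjusted over the list alone; median -0.63, adjusted p = 0.00112, and adjusted p = 0.237 with an estimated correlation). Tnfrsf25 and Cd5 of the CD4 T cell list were lower at -1.11 and -0.48, and B cell markers were lower in 3 of 10 and not called as a list (adjusted p = 0.309). In total 2917 genes were called, 941 higher and 1976 lower, with 430 at a log2 fold change of at least 1. The share higher, 32.3%, was 46.4% with quantile normalization and 14.1% with protein-coding genes alone, rescaled. The count was 4947 from the 6 libraries compared.

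The contrast of the inhibitor responses tested whether the genotypes differed in them. The inhibitor lowered cytokine genes and survival and apoptosis genes more in the libraries labelled KO. A lower response here is a larger fall or a smaller rise in those libraries than in WT. Cytokine and chemokine genes had a lower response in 7 of 16 and a higher in 0 (9 and 1 adjusted over the list alone; median difference -1.32 log2, adjusted p = 3.13e-06), with Csf2 at -4.62 (SE 0.51, adjusted p = 5.73e-05) and Il2 at -2.18, while Ifng was at -0.23 (adjusted p = 0.92). In WT, Csf2 was already low with gp33 (0.856, 1.93 and 2.81) and with inhibitor (0.639, 1.15 and 0.331), so it had little room to fall. Survival and apoptosis genes had a lower response in 10 of 17 and a higher in 0 (13 lower adjusted over the list alone; median -0.93, adjusted p = 2.71e-11). Inhibitory receptor genes had a lower response in 5 of 10 and a higher in 1 (6 and 1 adjusted over the list alone; median -0.39, adjusted p = 0.00289), and cholesterol synthesis genes a higher in 6 of 18 and a lower in 0 (11 higher adjusted over the list alone; median 0.41, adjusted p = 1.5e-06). These 4 calls held with an estimated correlation. Adm, which encodes adrenomedullin, was at 6.67 ± 1.85 (SD, n = 3) without and 8.61 ± 2.51 with inhibitor in WT, and at 27.8 ± 2.56 and 1.69 ± 1.39 in the libraries labelled KO. In total 999 genes were called, 335 with a higher and 664 with a lower response, with 273 at a difference of at least 1, and the share higher, 33.5%, was 13.4% with protein-coding genes alone, rescaled, and 46.2% with a filter 5 times as high. The count was 569 without KO stimulated replicate 2, 587 and 630 without WT stimulated replicate 3 or 2, and 648, 605 and 647 without replicate 1, 2 or 3 of the group labelled KO with inhibitor.

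Of the 1525 genes higher in the stimulated libraries labelled KO, 122 were also called higher with inhibitor, and of the 932 genes lower, 140 were also called lower. Independent calls would share 31 and 24 genes. A gene not called with inhibitor is not by itself a gene whose genotype difference was lost. The direct test is the genotype difference in the response to the inhibitor. It was called against the direction of the difference in stimulated cells in 585 of the 1525 genes and 258 of the 932. It was called in the same direction in 3 and 4. For the other genes a change was not shown. The log2 fold changes between genotypes with and without inhibitor had a Pearson r of 0.27 across genes, which are not independent replicates. The genotype difference in stimulated cells and the inhibitor effect in WT, which share the WT stimulated libraries, had an r of -0.04 and a covariance of -0.00608. Simulated noise for 3 unchanged groups, 1 of them shared by both differences, gave 0.5 and 0.0205. In such noise the r of 0.5 is fixed by the sharing, so only the covariances can be compared. Of the called genes, 171 were higher in the libraries labelled KO and lowered by the inhibitor in WT, against 79 for independent calls, and 43 were lower and then raised, against 31. Calls in the same direction were also more than independent ones, with 70 higher in both against 51 and 77 lower in both against 48. The genotype difference and the inhibitor effect in the libraries labelled KO, which share the stimulated libraries labelled KO, had an r of -0.78 and a covariance of -0.169, against -0.5 and -0.0205 for simulated groups, and 1205 genes were higher in the first and lower in the second. The shared groups were not split, since 3 libraries do not make 2 parts of at least 2. Sharing moves the second pair in opposite directions, so part of its excess over independent calls may be due to it, and moves the first pair in the same direction, against the excess of opposite calls.

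**Figure D4:**
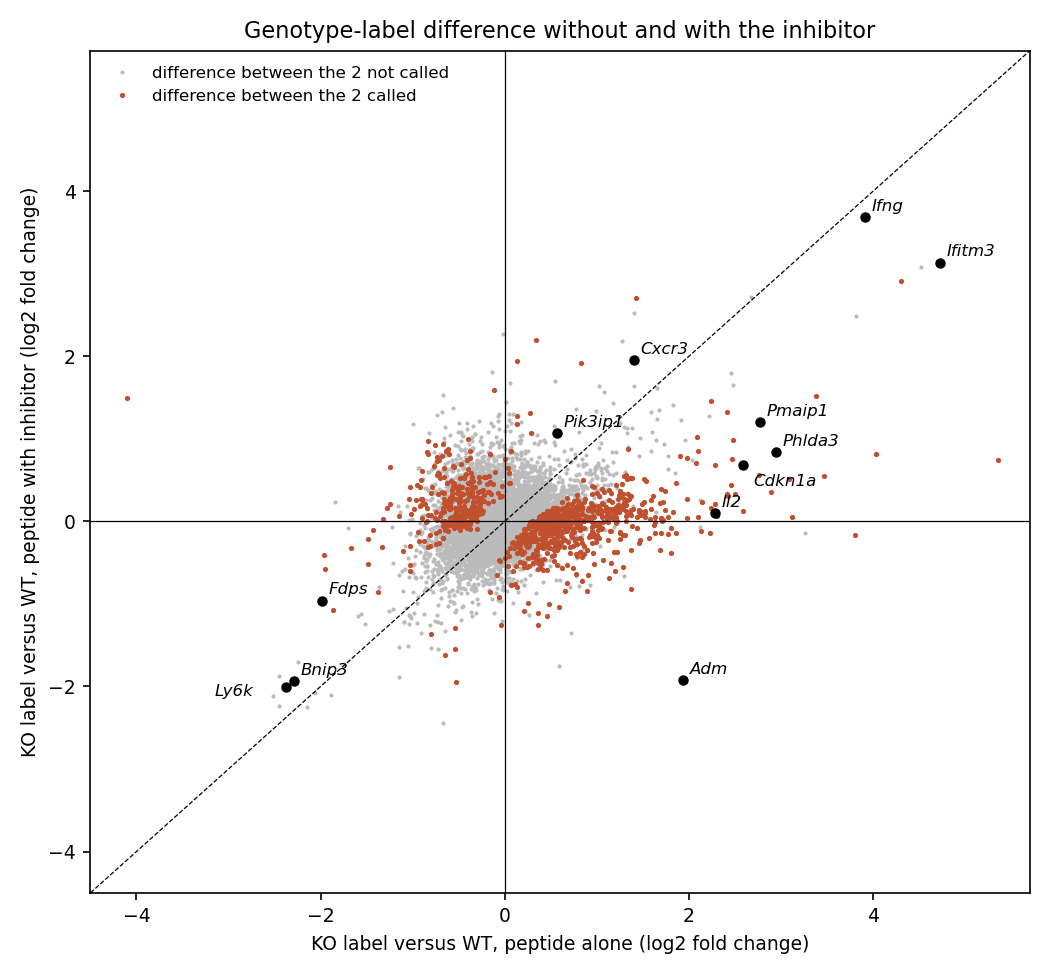
Log2 fold change between genotypes in stimulated cells (x axis) and with inhibitor (y axis), with a point for each of 10257 genes. The 999 genes whose response to the inhibitor differed between genotypes are coloured, and the 2 sets of fold changes had a Pearson r of 0.27.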

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

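The tests of replicate 2 of the WT group with inhibitor, of the interferon genes and of the Pik3ip1 label were chosen only after the result was seen, and the splits of the libraries before.

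Pik3ip1 went against the label: its log2 fold changes were 1.27, 0.57 and 1.07 in favour of the libraries labelled KO. The 3 other scalings tried (median-of-ratios, quantile, and protein-coding genes rescaled) do not account for it, since the smallest log2 fold change under them was 0.47. An exchange of the genotype labels could give the same direction in 3 of 3 conditions. The libraries labelled WT still held 40.7% of the level in those labelled KO without peptide, 47.5% with gp33 and 26.1% with inhibitor. An exchange alone would therefore not account for a loss of the transcript. Transcripts of the part of the gene left after a deletion could also be read, and the highest value was 78.9 in a library labelled KO. These 2 explanations cannot be told apart from values per gene, and reads over the deleted exons would be needed.

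Replicate 2 of the WT group with inhibitor had a mean correlation with its group of 0.961. Compared with the other libraries of its group, parent genes lay above their processed pseudogenes by a median of 0.54 log2 over 443 pairs, while for the 15 libraries of other groups this value lay between -0.06 and 0.07. A different division of reads between genes and copies is a possible explanation that fits this value, although what changed it is not known. An exchange with a library of another group is not supported, since over 500 genes it lay 0.19 of the way to the WT stimulated group and 0.21 of the way to the group labelled KO with inhibitor. Replicates 1 and 3 of the group had mean correlations of 0.978 and 0.979 with their own group, which includes replicate 2. Both correlated more with the group labelled KO with inhibitor. Because groups hold 3 libraries, no test for outlying libraries was made and replicate 2 was kept.

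Interferon response genes were higher in the unstimulated libraries labelled KO by a median of 1.37 for the interferon gamma list. Cells or RNA from the stimulated libraries labelled KO are not a likely source, since 14 of 17 called genes lay above every stimulated library labelled KO. A lower share of CD8 T cells with more of every other cell type is not a likely explanation, since B cell markers were lower at -0.86 and myeloid markers higher at 2.06. A lower share with fewer B cells and more myeloid cells would give these same directions, so it is not excluded by them. RNA of the cells that bring Lyz2 is not likely either, since the ratio of the highest to the lowest unstimulated library labelled KO was 2.69 for Lyz2 and had a median of 1.16 for the called genes, with 16 of 17 under 1.64, the square root of the Lyz2 ratio. Interferon made in the culture by either cell type was not tested and stays open.

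Pf4, a platelet gene that the naming rule does not give and that was looked at only after the result was seen, was at 22.5, 20.7 and 10.2 in the unstimulated libraries labelled KO and at 0.19, 0.114 and 0 in WT.

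Other splits of the libraries into groups of 3 gave at most 82 calls between the unstimulated groups, where the labels gave 1326. The highest count from another split was 1 for the stimulated groups and 0 for the groups with inhibitor. For stimulation it was 0 in WT and 1 in the libraries labelled KO, and for the inhibitor 0 and 0. For the differences in response it was 3 for stimulation and 0 for the inhibitor. In each of the 9 comparisons the labelled split was 1 of 10 splits, which are too few for a share under 0.05. Every other split mixes the labels on both sides, so a true difference widens the spread and lowers the count. The low counts of these splits therefore do not measure chance.

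The response to stimulation differed between genotypes in 2595 genes. Of the genes given by the naming rule for this contrast, which leaves out genes of low mean level, the largest differences were 3.27 for Phlda3, 2.77 for Mdm2, 2.64 for Adm, 2.34 for Pmaip1 and 2.27 for Ccng1, all p53 targets but Adm. The smallest were -3.94 for Iigp1, -3.33 for the metallothionein Mt1, -3.13 for Ifitm2, -3.09 for Ly6a and -2.89 for Gbp2. Lists with a higher median response in the libraries labelled KO were FOXO targets at 0.97, B cell markers at 0.89, stress and immediate early genes at 0.88, survival and apoptosis genes at 0.67 and naive and memory genes at 0.47. B cell markers and naive and memory genes fell with stimulation in both genotypes, so for them this was a smaller fall. Lists with a lower median response were the interferon gamma response at -1.56, glycolysis at -1.11, cholesterol synthesis at -0.57, cell cycle at -0.50 and fatty acid synthesis at -0.22. With an estimated correlation the adjusted p was 0.213 for B cell markers, 0.252 for stress, 0.119 for naive and memory genes, 0.323 for cell cycle and 0.213 for fatty acid synthesis.

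The response to the inhibitor differed between genotypes in 999 genes. Of the genes given by the naming rule for this contrast, the largest differences were 1.81 for Ly6a, 1.71 for Iigp1, 1.61 for Calhm6, 1.47 for the mitotic gene Ube2c and 1.46 for the tubulin gene Tuba4a. The calls for Iigp1 and Ube2c each ended without 9 of 12 libraries left out in turn, at adjusted p of 0.0504 to 0.0776 and 0.0502 to 0.0913. The smallest by that rule, which leaves out genes of low mean level such as Csf2 at -4.62, were -3.86 for Adm, -2.24 for Perp, -2.20 for the costimulatory ligand Tnfsf9, -2.18 for Il2 and -2.11 for Phlda3. Lists with a lower median response were cytokines and chemokines at -1.32, survival and apoptosis at -0.93, stress and immediate early genes at -0.78, the type I interferon response at -0.63, FOXO targets at -0.45, inhibitory receptors at -0.39, MHC class II at -0.21, cytotoxic effector genes at -0.18 and amino acid uptake and one-carbon metabolism at -0.18. Cytokines and chemokines fell with the inhibitor in both genotypes, so for them this was a larger fall in the libraries labelled KO. Lists with a higher median response were the interferon gamma response at 0.46, cholesterol synthesis at 0.41, fatty acid synthesis at 0.38, glycolysis at 0.13 and cell cycle at 0.10. With an estimated correlation only the cytokine, survival, inhibitory receptor and cholesterol lists held. The adjusted p was then 0.0756 for the stress, type I interferon, FOXO, cytotoxic effector and fatty acid lists, 0.163 for the interferon gamma response, 0.233 for amino acid uptake, 0.417 for MHC class II, 0.431 for glycolysis and 0.664 for cell cycle. The calls for MHC class II, amino acid, glycolysis and cell cycle lists ended without some of the libraries, at adjusted p between 0.0504 and 0.176.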

How the results depend on the processing

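The pseudocount of 0.05, the protein-coding setting and the removal of replicate 2 of the WT group with inhibitor are tests chosen only after the result was seen. Planned tests on whole reads were not run, because the deposited values are not whole reads. Counts follow the order genotype without peptide, with gp33 and with inhibitor, stimulation in WT and in the libraries labelled KO, inhibitor in WT and in the libraries labelled KO, and the differences in response to stimulation and to inhibitor. With a log2 fold change of at least 1 they were 225, 327, 82, 3475, 2806, 80, 430, 626 and 273. With no filter on low values, 2546 genes were called without peptide, 3755 with gp33, 12251 and 11430 for stimulation in WT and in the libraries labelled KO, 4389 for the inhibitor in the latter and 4123 for the difference in response to stimulation; this setting tests more genes. With a filter 5 times as high, which left 5496 genes, these were 697, 1468, 4267, 4050, 1736 and 1429, and the difference in response to the inhibitor was 660. With protein-coding genes only, rescaled, 4594 and 4528 genes were called for stimulation, and fewer genes were tested. From the libraries of the groups compared only, the counts were 466, 3968 and 109 between genotypes and 263 and 4947 for the inhibitor. The main model shares 1 spread per gene over groups that varied unequally. Mean correlations with the own group were 0.982 to 0.986 without peptide, 0.993 to 0.996 with gp33 and 0.961 to 0.979 in WT with inhibitor. The main counts may thus be too high where libraries varied more and too low where they varied less. Whether this gave the change was not tested separately. With the replicate number as a block they were 1199, 2266, 418, 7571, 6975, 649, 2788, 2486 and 790. With a library of the compared groups left out in turn the counts lay between 1003 and 1439, 1582 and 2108, 261 and 544, 7066 and 7356, 6486 and 6808, 433 and 995, 2029 and 2458, 1965 and 2823, and 569 and 1477. The list calls lay between 106 and 119. Replicate 2 of the WT group with inhibitor was also removed from the comparisons that do not use it. The counts were then 2101 without peptide, 3647 with gp33, and 8182 and 7697 for stimulation in WT and in the libraries labelled KO. For the inhibitor in the latter the count was 4053, and for the difference in response to stimulation 3882. Of 112 list calls, 46 held in camera with an estimated correlation, and 0 list results changed direction in any setting. List calls lost were 13 with the higher filter, 9 with quantile normalization, 9 with protein-coding genes only, 7, 3 and 4 at pseudocounts of 0.05, 0.25 and 4, 5 with median-of-ratios scaling, 3 with the block, 2 with no filter, and 38 over all libraries left out in turn. The correlation across genes of the genotype difference in stimulated cells with the inhibitor effect in WT, -0.039, was -0.009 and 0.023 at pseudocounts of 0.25 and 0.05, -0.108 with the higher filter, -0.227 with protein-coding genes only, and -0.057 to 0.04 with a library left out; its sign is not settled and the cause was not tested. Over 15266 alternative values of 633 gene and 189 list results, 695 calls were lost, 374 of them with a library left out, 85 from the libraries of the groups compared only, 61 at a pseudocount of 0.05, 32 with quantile normalization and 22 with the block. In 1 gene result the direction changed. For Cdkn1a, genotype difference in the response to stimulation, the value was 1.67 in the main model (limma adjusted p = 7.81e-05). It was -0.432 at pseudocount 0.05 (adjusted p = 0.555), a setting that widens the fold changes of genes with values near 0. The direction of this result therefore depends on the pseudocount.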

Other observations

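The tests of the p53 and hypoxia lists were chosen only after the result was seen. Ly6k, a member of the Ly6 family, and Bnip3 differed between genotypes with and without inhibitor. Ly6k was lower in the libraries labelled KO without peptide (log2 fold change -1.14), with gp33 (-2.38) and with inhibitor (-2.01). Bnip3, induced by low oxygen, was lower with gp33 (-2.28) and with inhibitor (-1.93). Cdkn1a changed with the inhibitor by a log2 fold change of -1.87 in WT and -3.78 in the libraries labelled KO, and its difference in response was -1.91 (adjusted p = 6.35e-05).

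Hypothesis: stimulated libraries labelled KO may have had more p53 activity, part of which may have depended on PI3K delta. Of 13 p53 targets not named before, 10 were higher and 1 lower with gp33 in the libraries labelled KO (median log2 fold change 1.01, p = 5.43e-08 by limma camera with the preset correlation), and with inhibitor 10 were lower and 1 higher (median -1.11, p = 1.72e-07). Both held at an adjusted p of 0.01 with an estimated correlation over the 18 tests. Among them with gp33 were Plk2 at 2.46, Fas at 1.43, Zmat3 at 1.29 and Bbc3 at 1.04. Not named before means only that the naming rule did not give the gene. Fas and Bbc3 are also in the survival and apoptosis list, which was called higher with gp33 and lower with inhibitor. The test of these p53 targets is therefore not separate from that result. Without peptide the list was not called (adjusted p = 0.296). Both tests above share the stimulated libraries labelled KO, which moves them in opposite directions, so they are not independent. In WT the inhibitor also lowered the list (5 lower and 0 higher, adjusted p = 0.00814 by camera, and 0.094 with an estimated correlation). Between genotypes with inhibitor the list was still higher, by a median of 0.13 (adjusted p = 0.0207 by camera, and 0.136 with an estimated correlation). RNA cannot tell p53 activity from other regulators of these genes, and p53 protein or a p53-deficient control would be needed.

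Hypothesis: the stimulated libraries labelled KO may have had a weaker hypoxia response. Of 11 hypoxia targets not named before, 8 were lower and 2 higher with gp33 in the libraries labelled KO (median log2 fold change -0.53, p = 4.04e-05, adjusted p = 0.094 with an estimated correlation), so this could not be told from chance. Of the hypoxia targets named before, Bnip3 was lower with gp33 (-2.28), while Adm was higher (1.94, adjusted p = 0.000191), which goes against the hypothesis. With inhibitor, between genotypes, 8 were lower and 0 higher (median -0.82, p = 1.49e-13, adjusted p = 0.01 with an estimated correlation). The inhibitor in the libraries labelled KO gave p = 0.044 with the preset correlation (adjusted p = 0.066). The difference between genotypes in the response to the inhibitor was not called (adjusted p = 0.292). How fully PI3K delta was inhibited, oxygen in the cultures, cell density and HIF1A protein were not measured.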
